A study of Mus musculus with 6 samples.

How the data were processed

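Liver NK cells of wild-type mice were profiled by RNA sequencing in 6 libraries, 3 from PBS-treated and 3 from metformin-treated mice, on day 3. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with SMART-seq mRNA chemistry, which copies polyadenylated RNA by template switching and PCR. How the NK cells were isolated, and by which gate, is not given in the sources used here. The submitters' processing notes name DRAGEN, with no version, and the builds GRCm39 and mm10, with no role. The authors deposited a single table of 55414 genes with a gene identifier, symbol, type, position and length. Of its genes 52081 are also in GENCODE M21, and 1494 of these (2.87%) have the same position there, on GRCm38, so coordinates are given as the table holds them and are not those of GRCm38 (mm10).

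For each library the deposited table gives an estimated count per gene, which is not whole, and a TPM value. The authors' estimated counts are not normalized and sum to 22152167 to 30161214 per library. The deposited TPM values were scaled by the authors to the same total in every library and keep no depth. Whether strand was used, how reads shared between near-identical genes were assigned and which filters were applied is not given in the sources used here. Of the columns of values per sample, 0 were left without a sample. Genes were keyed by identifier, because 901 symbols occur more than once.

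Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr, no covariate) in R 4.3.3, with limma 3.58.1 for set tests, and DESeq2 1.42.0. The filter left 15527 genes. The common biological coefficient of variation was 27.3%. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05, over all genes or, where said, over a list alone. CPM values use TMM-scaled library sizes, and fold changes are metformin against PBS. The median log2 fold change of all genes tested was 0.01 (0.0053) with TMM, 0.02 with library size only, 0.05 with upper quartile scaling and -0.00017 with DESeq2 size factors.

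A total of 26 lists of NK cell and metformin-related programs and 18 lists of cell type markers were fixed before the data were examined, as were the main test, the other settings to be tried and the rule for named genes. Of 1085 list symbols 1064 were found, 4 of them through a RefSeq synonym, which gave 1068 entries. Each list was tested with camera (preset correlation 0.01), and beside it with camera with the correlation estimated per list, with fry, which tests whether the genes of a list move on balance 1 way, and against 10000 random lists matched on mean expression in 20 bins. Marker genes were also summed as CPM per library. Sums, scores and quality measures were compared with two-sided exact permutation tests, where 0.1 is the smallest p. Named genes were the 5 genes with the smallest p in each direction (with a mean of at least 5 CPM, groups that do not overlap, and a protein-coding gene), since edgeR called 0, 14 genes fixed in advance, and per program list up to 4 members that passed or, if none passed, the 2 with the smallest p, 81 genes in all. That "passed" in the last part covers a call over the list alone was settled after the values were seen. Genes named outside this rule were chosen after their values were seen. Some genes and pathways that these rules select are not reported here.

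The tests were tried on simulated counts for this comparison, drawn for 15527 genes from the means and library sizes of the 6 libraries, with 200 genes changed, in 10 simulations. At folds of 1.5, 2, 3 and 4, edgeR recovered 12.6%, 45.8%, 65.2% and 74.4% of the changed genes with 7.84% false calls, DESeq2 28.6%, 55.8%, 74.8% and 82.0% with 27.4% false calls, and limma-voom 11.2%, 45.0%, 64.4% and 73.4% with 7.25% false calls. With no gene changed, edgeR called 0 to 2 genes, DESeq2 10 to 31 and limma-voom 0 to 1. When 1 list was shifted by 0.5 on the log2 scale, in 1 simulation, all 4 set tests called it and called 0 other lists. Simulated genes were drawn independently, while the estimated correlation in the real data reached 0.90, in mitochondrially encoded genes. The simulation thus cannot show how often a list whose genes vary together is called wrongly, nor the rate of false gene calls in the real data. Replicate libraries of a group differed by more than sampling noise (chi-square per degree of freedom 13.8 to 57.7), so none was treated as a repeat deposit.

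Other settings fixed in advance were DESeq2, limma-voom without and with sample quality weights, 3 other normalizations, no filter, a filter of 5 CPM in 3 libraries, protein-coding genes only, no marker genes, a thresholded test at a fold of 1.5, an adjusted p of 0.1, the other set tests, the replicate number as a block, the mean of log2 CPM in place of summed markers, and each library left out. Settings added after the data were seen were a lowess offset (span 0.3) for gene length and GC content, available for 99.7% of the genes tested, a covariate from 7 genes restricted to T cells, limma-trend on log2(TPM + 1), and the estimated correlation together with the length and GC offset or without metformin 3. Reactome pathways with 10 to 200 genes tested were added after the data were seen too. The planned settings for files without counts did not apply.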

Results

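Messenger RNA was measured in natural killer (NK) cells from the livers of wild-type mice, innate lymphocytes that kill tumour and infected cells. The design has 2 groups of 3 libraries, taken on day 3: cells from mice given phosphate-buffered saline (PBS), the control, and cells from mice given metformin, a glucose-lowering drug that inhibits respiratory complex I, at 200 mg per kg for 3 days. The table held 27263681, 24838302 and 30161214 estimated reads for PBS libraries 1, 2 and 3, and 22983788, 24266803 and 22152167 for metformin libraries 1, 2 and 3. All 3 metformin libraries were shallower than all 3 PBS libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). Between 20297 and 21576 genes had at least 1 read per library, and all pairs of libraries correlated at 0.953 to 0.974 in log2 CPM (read counts scaled to the library's total; across genes, which are not independent replicates). Nothing in the labels says that the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. Reads were made by PCR without molecular identifiers, so PCR copies cannot be told from separate molecules. Standard errors (SE) are those of edgeR's fit, which includes the spread between libraries.

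The libraries were not alike in quality. Metformin 3 had the lowest mean correlation with the others (0.956, against 0.964 to 0.968), and lay alone at 70.0 on the first principal component, which held 29.8% of the variance. Its share of mitochondrial reads was 0.720%, against 0.429% to 0.515% in the other 5 libraries. It also had the most hepatocyte marker reads, 1124 CPM summed over 26 genes, against 381 to 607 CPM. The Spearman correlation of expression, relative to the mean of all libraries, with gene length was 0.0519, 0.290 and 0.327 in PBS 1, 2 and 3 and -0.110, 0.131 and -0.422 in metformin 1, 2 and 3 (two-sided exact permutation p = 0.2 between groups). Short genes thus read higher in metformin 3 than in the other libraries.

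The comparison asked how metformin changed gene expression in liver NK cells; the title of the series names the death ligand TRAIL and antitumour activity. Genes that mark liver type 1 innate lymphoid cells (ILC1), the tissue-resident relatives of NK cells, were higher after metformin: 15 of 22 rose and 0 fell, adjusted over the list alone. Genes of circulating conventional NK cells were lower: 16 of 22 fell and 0 rose, adjusted over the list alone. With an estimated correlation camera called both lists (adjusted p = 0.047 each). These calls were lost when the gene length and GC trend was removed (adjusted p = 0.086 each), and the ILC1 call without metformin 3 (adjusted p = 0.095). The sum of T cell markers was higher with metformin too, 1815 CPM against 1204 CPM with PBS (exact permutation p = 0.1). Of 40 cell cycle genes, 22 fell and 0 rose, adjusted over the list alone, but the call of the list was lost with an estimated correlation (adjusted p = 0.366) and by fry (adjusted p = 0.198). PBS 1 stood apart in this list (score 0.76, against 0.18 and 0.07 in PBS 2 and 3), and its median of -0.77 was -0.45 without PBS 1. Tnfsf10, which encodes TRAIL, averaged 105 ± 8.61 CPM with PBS and 140 ± 19.7 CPM with metformin (SD, n = 3 each). Adjusted over all 15527 genes tested, no single gene passed in edgeR's quasi-likelihood test.

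At an adjusted p of 0.05, edgeR called 0 genes, with a smallest adjusted p of 0.125. At an unadjusted p under 0.05 edgeR gave 1610 genes, 821 higher and 789 lower, where chance would give 776. DESeq2 called 299 genes (147 higher, 152 lower), limma-voom 0 and limma-voom with sample quality weights 36 (27 higher, 9 lower). Their counts at an unadjusted p under 0.05 were 1748, 1679 and 2061. In data simulated with no changed gene DESeq2 called 10 to 31 genes and edgeR 0 to 2. Those genes were drawn independently and without the gene length trend of the real libraries, so the false calls here may differ. The 2 groups did not overlap in 2969 genes (19.1%), against the 10% that chance gives with 3 against 3 libraries.

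The genes closest to the threshold over all genes did not pass it. Tmem273, a membrane protein gene (ENSMUSG00000041707.9, chromosome 14, 32507920 to 32539941), averaged 32.8 ± 2.12 CPM with PBS and 77.4 ± 10.5 CPM with metformin, a log2 fold change of 1.24 (SE 0.12; edgeR adjusted p = 0.125). With metformin 3 left out, edgeR called Tmem273 alone (adjusted p = 0.037). The other 4 genes with the smallest p on the higher side had an edgeR adjusted p of 0.168. Tigit, an inhibitory receptor of NK and T cells, averaged 26.0 CPM with PBS and 49.3 CPM with metformin. Pik3ip1, an inhibitor of PI3 kinase, averaged 43.6 and 68.0 CPM, and Slc2a8, a glucose transporter, 32.1 and 62.8 CPM. Trat1, an adaptor of the T cell receptor, averaged 2.76 and 7.88 CPM. On the lower side the 5 genes also had an edgeR adjusted p of 0.168. Eomes (ENSMUSG00000032446.15, chromosome 9, 118307280 to 118315200), a transcription factor of conventional NK cells, averaged 327 ± 15.2 CPM with PBS and 212 ± 4.04 CPM with metformin, a log2 fold change of -0.63 (SE 0.09). Tagap, a GTPase-activating protein of lymphocytes, averaged 232 and 136 CPM, and Sgk1, a kinase downstream of PI3 kinase, 94.9 and 60.0 CPM. Dglucy, a mitochondrial D-glutamate cyclase, averaged 27.1 and 14.1 CPM, and Espl1, the protease separase that parts sister chromatids, 16.2 and 5.27 CPM.

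Il7r, the interleukin-7 receptor, rose from 46.4 to 77.6 CPM, and Podnl1 from 60.2 to 98.5 CPM, adjusted over the ILC1 list alone (adjusted p = 0.0019 each, edgeR). Zfp683, the transcription factor Hobit of resident lymphocytes, rose from 28.6 to 47.1 CPM and Inpp4b, a phosphoinositide phosphatase, from 92.1 to 138 CPM (adjusted p = 0.0025 each, edgeR). Itga1, the integrin CD49a that defines liver ILC1, rose by a log2 fold change of 0.50 (SE 0.12) and Cxcr6, a chemokine receptor that holds lymphocytes in the liver, by 0.64 (SE 0.12), both adjusted over the list alone (adjusted p = 0.0063 and 0.0025, edgeR). Tnfsf10 (ENSMUSG00000039304.12, chromosome 3, 27371177 to 27396576) was among the 15, with a log2 fold change of 0.42 (SE 0.12; adjusted p = 0.016 when adjusted over the list alone, adjusted p = 0.360 over all genes, edgeR). It is also a member of the list of cytotoxic effectors and death ligands, over which it did not pass (adjusted p = 0.127). Cd69, an activation and retention receptor, did not pass (log2 fold change -0.06, SE 0.09; -0.19 to 0.07 over the settings tried). The list median was a log2 fold change of 0.54, and camera with a preset correlation called it (adjusted p = 6.1e-24). The call held with an estimated correlation (adjusted p = 0.047) and by fry (adjusted p = 0.019). It was lost with an estimated correlation when the gene length and GC trend was removed (median 0.56, adjusted p = 0.086) or metformin 3 was left out (median 0.49, adjusted p = 0.095). Of the 22 genes, 10 are also members of other lists. T cell markers moved with this group: their sum was 1204 ± 87.1 CPM with PBS and 1815 ± 157 CPM with metformin (SD, n = 3, two-sided exact permutation p = 0.1). That sum includes Cd3g, which NK cells also transcribe. The sum of 7 genes restricted to T cells overlapped between the groups (15.3 to 81.6 CPM with PBS, 36.2 to 166 CPM with metformin).

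Among conventional NK genes, Eomes fell as given above (adjusted over the list alone, adjusted p = 0.0019, edgeR). Itga4, an integrin subunit, fell from 445 to 302 CPM and Klf2, a transcription factor that drives lymphocyte egress, from 544 to 425 CPM (adjusted p = 0.019 each, adjusted over the list alone, edgeR). Itga2, the integrin CD49b of conventional NK cells, fell by 0.64 on the log2 scale (SE 0.19; adjusted p = 0.023 over the list alone, edgeR). Tbx21, the transcription factor T-bet, did not pass (log2 fold change -0.14, SE 0.10; -0.28 on TPM and -0.07 without metformin 3). Of 5 Klra (Ly49) receptor genes in the list, Klra1, Klra3, Klra4 and Klra8 had log2 fold changes from -0.46 to -0.43 and Klra9 0.02; these genes are near-identical copies whose reads can be split wrongly, so their values are uncertain. The list median was a log2 fold change of -0.44 (camera adjusted p = 8.4e-17). The call held with an estimated correlation (adjusted p = 0.047) and by fry (adjusted p = 0.019). With an estimated correlation it was lost when the length and GC trend was removed (median -0.45, adjusted p = 0.086). The list shares 10 of its genes with other lists. Of 15 monocyte markers 4 fell adjusted over the list alone, among them Ccr2, from 458 to 331 CPM, which NK cells also express (log2 fold change -0.47, or -0.31 with the length and GC trend removed). The camera call of that list was lost with an estimated correlation (adjusted p = 0.210), and its sum was 941 CPM with PBS and 857 CPM with metformin (exact p = 0.5), with metformin 3, at 1103 CPM, above every PBS library; the log2 difference of the sum was -0.16, and -0.36 without metformin 3, -0.10 without PBS 2, -0.08 without metformin 1 and -0.04 without metformin 2.

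**Figure D1:**
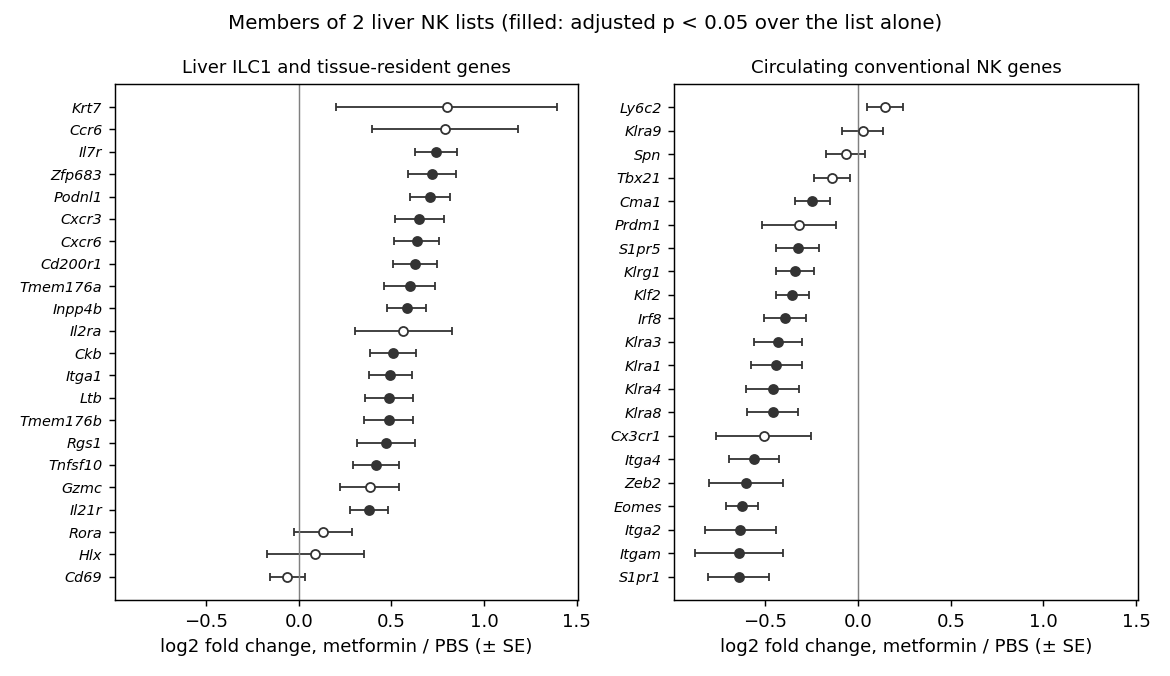
Log2 fold change (metformin minus PBS) of the 22 liver ILC1 genes and of the 22 conventional NK genes except 1 that is not drawn, with its standard error from edgeR (n = 3 libraries per group). The ILC1 genes had a median of 0.54 and the conventional NK genes a median of -0.44, over all 22 genes each; filled points mark genes that passed when adjusted over the list alone.

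Cytotoxic effectors and death ligands held 0 of 25 genes that passed over the list alone by edgeR, 5 genes at an unadjusted p under 0.05, all higher, and a list median of 0.16 (camera adjusted p = 0.046). The call was lost with an estimated correlation (adjusted p = 0.530) and without PBS 1, PBS 3, metformin 2 or metformin 3 (adjusted p = 0.105, 0.191, 0.086 and 0.081); the median was 0.080 without metformin 3, 0.075 with the length and GC trend removed (adjusted p = 0.378) and 0.015 on the deposited TPM (adjusted p = 0.198). Gzmb, the protease granzyme B, averaged 2383 ± 366 CPM with PBS and 3345 ± 467 CPM with metformin, a log2 fold change of 0.49 (SE 0.14; edgeR adjusted p = 0.353). Gzma, granzyme A, averaged 4495 and 5035 CPM (log2 fold change 0.16, SE 0.12), and removal of the length and GC trend turned its sign (-0.03). Prf1, the pore-forming protein perforin, averaged 1914 and 1661 CPM (log2 fold change -0.20, SE 0.11), Fasl, the Fas ligand, 486 and 544 CPM (0.16, SE 0.09), and Ifng, interferon gamma, 73.9 and 68.8 CPM (-0.10, SE 0.15). Over the settings tried the log2 fold changes were -0.034 to 0.24 for Gzma (0.023 without metformin 3, 0.11 without PBS 3), -0.34 to -0.11 for Prf1 (-0.34 on TPM, -0.11 without metformin 3), 0.057 to 0.21 for Fasl (0.057 on TPM) and -0.25 to 0.0078 for Ifng. None of these genes, nor Tnfsf10, passed over all genes or over this list. The receptor of TRAIL, Tnfrsf10b, was at 0.912 ± 0.413 CPM with PBS and 1.10 ± 0.493 CPM with metformin. Its log2 fold change was 0.26 (SE 0.53), and -0.18 to 0.69 with 1 library left out. With a SE above its fold change, Tnfrsf10b could not be told from unchanged. Its list of apoptosis regulators had a median of 0.02 and a mean of -0.06 with camera upward (adjusted p = 0.801), and 1 of 26 genes passed over the list alone, Bcl2a1b, a survival factor (log2 fold change 0.58, or 0.32 with the length and GC trend removed).

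**Figure D2:**
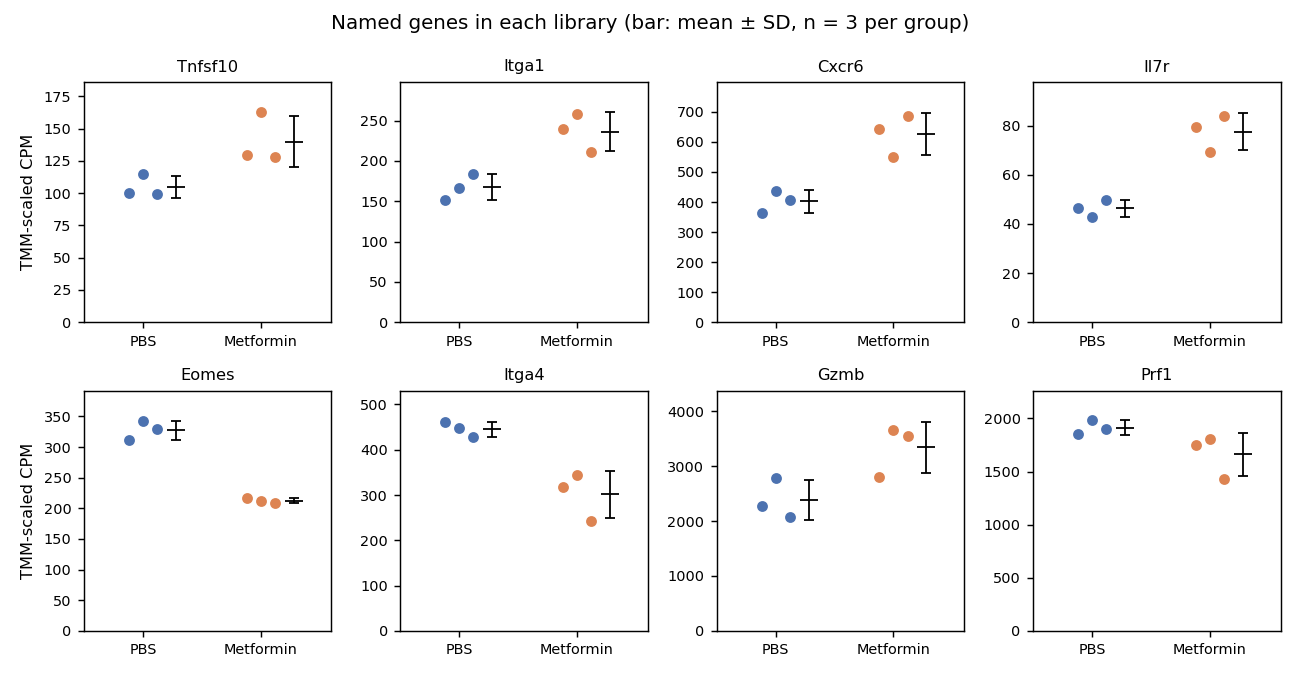
CPM of named genes in each library (points), with the mean and SD of the 3 PBS and the 3 metformin libraries (bars); each panel has its own linear axis from 0. Tnfsf10 averaged 105 CPM with PBS and 140 CPM with metformin, and Eomes 327 and 212 CPM.

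Inhibitory receptors and checkpoints were higher as a group, with a median of 0.26 (camera adjusted p = 5.8e-05), and the call was lost with an estimated correlation (adjusted p = 0.366). On the deposited TPM the median was 0.11 (adjusted p = 0.0038). T cell markers moved with this group too: their sum lay between 1105 and 1267 CPM in the PBS libraries and between 1650 and 1962 CPM in the metformin libraries (exact p = 0.1). For 7 genes restricted to T cells the sums overlapped between the groups (15.3 to 81.6 CPM with PBS, 36.2 to 166 CPM with metformin). Over the list alone 5 of 18 rose: Tigit, Cd200r1, Entpd1 (the ectonucleotidase CD39), Klrb1b and Pdcd1 (PD-1). Klra7 fell. Activating and adaptor receptors were not called (median 0.10, camera adjusted p = 0.071; called without metformin 1 or 2, adjusted p = 0.049 and 0.042), and 2 of 25 rose over the list alone: Cd160 (289 to 417 CPM) and Hcst, the adaptor DAP10 (84.2 to 120 CPM). The log2 fold change of Hcst was 0.51, against 0.044 with the length and GC trend removed and 0.28 on TPM. Among cytokine receptors and JAK-STAT components (median -0.11, camera adjusted p = 0.467) 4 of 30 rose over the list alone. Of these Socs2 (58.3 to 98.6 CPM), Socs1 and Cish are feedback inhibitors of cytokine signalling, and Il21r is the interleukin-21 receptor. Both chains of the interleukin-18 receptor fell over the list alone, Il18rap from 682 to 451 CPM and Il18r1 from 67.0 to 50.2 CPM. Chemokines and their receptors went both ways (median 0.10, camera adjusted p = 0.407; median -0.10 without metformin 3): over the list alone Cxcr6, Cxcr3 and Xcl1, a chemokine that attracts dendritic cells, rose, and Ccr2, Cxcr4 and S1pr1, receptors of leukocyte traffic, fell. Xcl1 went from 209 to 329 CPM and Cxcr3 from 324 to 509 CPM. The log2 fold change of Xcl1 was 0.65, against 0.25 with the length and GC trend removed and 0.42 on TPM. Cxcr6, Cxcr3, Il21r and Cd200r1 are also members of the ILC1 list, and S1pr1 of the conventional NK list, so they are not separate results.

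Of 30 NK and ILC transcription factors, 2 rose over the list alone, Zfp683 and Maf (log2 fold change 0.48, or 0.30 on TPM), and 4 fell, Eomes, Klf2, Tcf7 and Irf8 (median -0.08, camera adjusted p = 0.084; called lower without PBS 1, adjusted p = 0.037). Among FOXO targets and PI3K-AKT regulators, Il7r and Pik3ip1 rose and 3 genes fell, Klf2 and S1pr1 among them, over the list alone (5 of 27; median -0.06, camera adjusted p = 0.281). Each of these lists shares 9 of its genes with other program lists, those of ILC1 and conventional NK genes among them.

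Cell cycle genes had a list median of -0.77, which camera called (adjusted p = 2.1e-25), and the call was lost with an estimated correlation (adjusted p = 0.366) and by fry (adjusted p = 0.198). Mki67, the proliferation antigen Ki-67, fell from 65.0 ± 15.4 to 34.2 ± 5.02 CPM (SD, n = 3; adjusted over the list alone, adjusted p = 0.019, edgeR). Top2a, a topoisomerase of dividing cells, fell from 89.3 to 41.8 CPM, E2f2, a transcription factor of cell cycle entry, from 24.9 to 12.1 CPM, and Cenpe, a kinetochore motor, from 13.9 to 7.73 CPM, each with the same adjusted p. PBS 1 had the highest score of this list (0.76, against 0.18 and 0.07 in PBS 2 and 3 and -0.42 to -0.20 with metformin), and without PBS 1 the median was -0.45.

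Nuclear genes of respiratory complex I, the complex that metformin inhibits, had a list median of 0.28 (camera adjusted p = 9.1e-13), and the call was lost with an estimated correlation (adjusted p = 0.554). Over the list alone 5 of 36 rose, among them Ndufa3 (59.4 to 92.7 CPM), Ndufa5 (23.0 to 35.7 CPM), Ndufa1 and Ndufa13. With the length and GC trend removed the log2 fold changes of these 4 went from 0.64, 0.64, 0.50 and 0.45 to 0.36, 0.40, 0.037 and 0.28. Complexes II to V had a median of 0.26 (camera adjusted p = 3.7e-09; adjusted p = 0.584 with an estimated correlation), with 0 of 41 past the threshold over the list alone by edgeR and 18 higher at an unadjusted p under 0.05; the smallest p were those of Atp5j2, a subunit of ATP synthase, and Cox6a1, a subunit of cytochrome c oxidase (log2 fold changes 0.51 and 0.43; Cox6a1 0.068 with the length and GC trend removed). Ribosomal proteins had a median of 0.21 (camera adjusted p = 1.8e-12; adjusted p = 0.584 with an estimated correlation), with 0 of 77 over the list alone by edgeR and 20 higher at an unadjusted p under 0.05, led by Rps29 (0.62) and Rpl38 (0.56), at 0.18 and 0.10 with that trend removed. Proteins encoded in mitochondrial DNA had a median of 0.23 (camera adjusted p = 0.012; adjusted p = 0.616 with an estimated correlation), with 0 of 13 over the list alone by edgeR and 1 higher at an unadjusted p under 0.05, mt-Co2 (0.30, or -0.00040 with that trend removed and 0.17 without metformin 3). These groups moved with gene length: across genes the Spearman correlation of log2 fold change with gene length was -0.395, and metformin 3 scored highest, at 0.33 for complex I and 0.35 for ribosomal proteins. With the length and GC trend removed, the medians were 0.065 for complex I (called with a preset correlation, adjusted p = 0.0094, though no list was called with an estimated one) and 0.020 for complexes II to V, and the calls of complexes II to V (adjusted p = 0.261), ribosomal proteins and mitochondrially encoded proteins (adjusted p = 0.458 each) were lost. On TPM the medians were 0.11, 0.086, 0.039 and 0.086 for complex I, complexes II to V, ribosomal and mitochondrially encoded proteins. Without metformin 3 the medians were 0.16, 0.14 and 0.069 for complex I, complexes II to V and ribosomal proteins, and the call of mitochondrially encoded proteins was lost (median -0.02, adjusted p = 0.980), as it was without PBS 2 (adjusted p = 0.052) or PBS 3 (adjusted p = 0.153).

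Cholesterol synthesis genes were lower, with a list median of -0.25 (camera adjusted p = 4.8e-06) and a call that was lost with an estimated correlation (adjusted p = 0.366). Over the list alone 6 of 24 fell (edgeR). Hmgcs1, an early enzyme of the pathway, fell from 66.7 to 47.7 CPM. Cyp51, a sterol demethylase, and Insig1, a sterol sensor, fell by 0.71 and 0.53 on the log2 scale. Without PBS 2, which had the highest score of this list (0.29), the median was -0.11. Glycolysis genes had a median of -0.07 (camera adjusted p = 0.046), and the call was lost with an estimated correlation (adjusted p = 0.584). It was also lost without PBS 2, metformin 2 or metformin 3 (medians -0.054, -0.094 and -0.056, camera adjusted p = 0.151, 0.084 and 0.114). Without PBS 1 or PBS 3 the median was -0.15 and -0.11, and on TPM -0.19. Over the list alone 2 of 25 fell: Slc16a1, a lactate transporter (27.1 to 14.4 CPM), and Pfkm, a phosphofructokinase (9.29 to 4.83 CPM). Fatty acid oxidation (median 0.02, camera adjusted p = 0.638) had 0 of 25 genes past the threshold over the list alone by edgeR and 4 at an unadjusted p under 0.05, Slc25a20 (0.40) and Acsl4 (-0.60) leading.

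AMP-activated protein kinase (AMPK), the energy sensor that metformin activates, was covered by the mRNA of 25 subunits, regulators and targets, which does not measure its activity. Their median was -0.10 (camera adjusted p = 0.086; called lower without PBS 1 or metformin 2, adjusted p = 0.032 and 0.019), with 0 past the threshold over the list alone by edgeR and 3 lower at an unadjusted p under 0.05, Prkab2 (-0.68) and Sesn2 (-0.40) leading. Prkaa1, the catalytic subunit, averaged 65.8 and 59.8 CPM (log2 fold change -0.14, SE 0.13; -0.025 without metformin 3, -0.21 without metformin 1 and -0.22 on TPM). The integrated stress response had a median of 0.00 (-0.0017; camera adjusted p = 0.407), and 1 of 29 fell over the list alone, Slc7a5, an amino acid transporter (log2 fold change -1.01). Immediate-early and NF-kB genes had a median of -0.02 (camera adjusted p = 0.284), and 1 of 35 fell over the list alone, Nr4a1, a nuclear receptor induced by antigen receptor signals (68.8 to 40.9 CPM).

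Heat shock and protein folding genes split (median 0.12, mean -0.06, camera upward with adjusted p = 0.696). Over the list alone the cytosolic chaperone genes Dnajb1 (258 to 155 CPM), Hspa1a and Hspa1b fell, and the endoplasmic reticulum genes Creld2 (76.6 to 105 CPM) and Sdf2l1 rose. Hspa1a (log2 fold change -1.34) and Hspa1b (-1.56) are near-identical copies, so the values of each are uncertain.

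Type I interferon response genes were not called (median -0.01, or -0.0078, with a mean of 0.02 and camera upward at adjusted p = 0.801), with 0 of 47 over the list alone by edgeR and 2 higher at an unadjusted p under 0.05, Isg20 (0.54) and Bst2 (0.48), at 0.35 and 0.22 with the length and GC trend removed. The list was called higher without PBS 2 or metformin 3 (medians 0.10 and 0.09, adjusted p = 0.032 and 0.016) and lower without metformin 2 (median -0.23, adjusted p = 0.0067). Interferon-gamma response genes had a median of 0.05 (camera adjusted p = 0.104; called higher without PBS 2 or metformin 3, adjusted p = 0.014 and 0.0086); over the list alone Socs1 rose and Gbp3, a guanylate-binding protein, fell (68.7 to 41.3 CPM). Antioxidant and NRF2 targets had a median of 0.07 (camera adjusted p = 0.407), with 0 of 25 over the list alone by edgeR and 3 at an unadjusted p under 0.05, Sod1 (0.44, or 0.26 without metformin 3) and Gclc (-0.26) leading. Lysosome and autophagy genes had a median of -0.02 (camera adjusted p = 0.284), with 0 of 30 over the list alone by edgeR and 3 lower at an unadjusted p under 0.05, Gaa (-0.40) and Atp6v1a (-0.31, or -0.60 on TPM) leading.

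**Figure D3:**
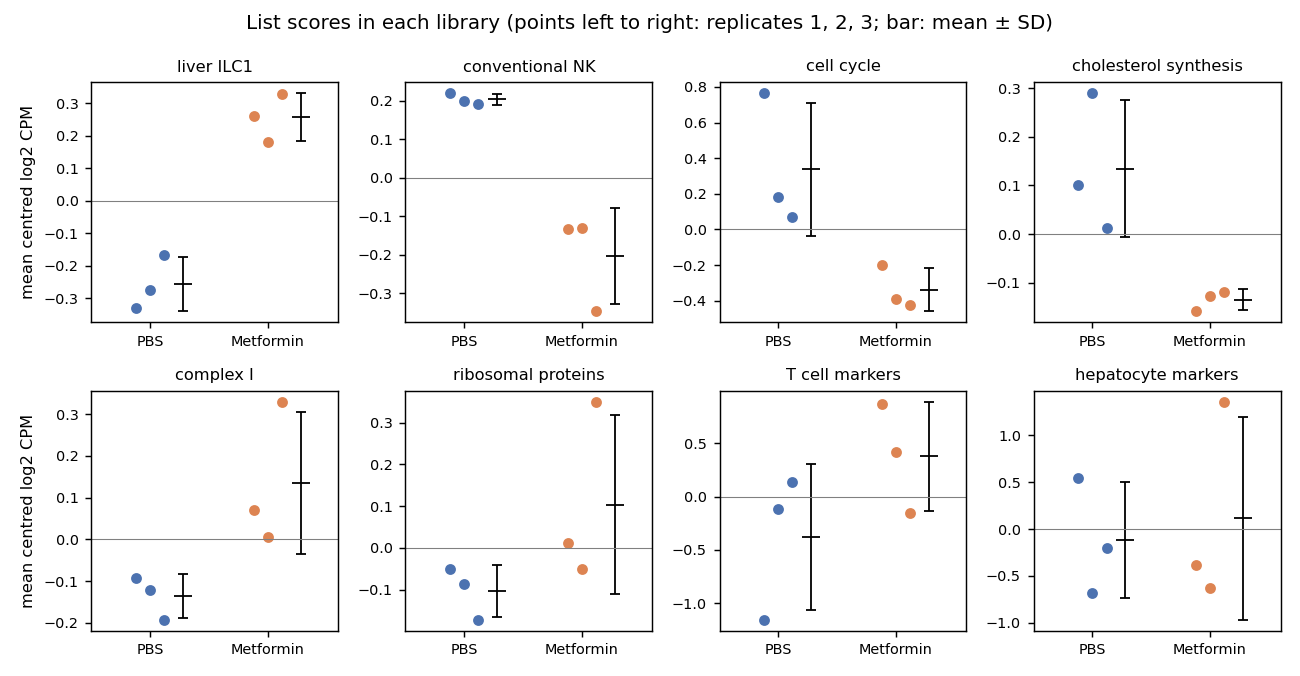
Score of 8 lists (mean log2 CPM of the list's genes, each relative to its mean over all 6 libraries) in every library (points), with the mean and SD of the 3 PBS and 3 metformin libraries; each panel has its own axis. The ILC1 score lay between -0.33 and -0.17 in the PBS libraries and between 0.18 and 0.33 in the metformin libraries.

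Camera called 11 of the 26 lists, 7 higher and 4 lower; with an estimated correlation 2 remained, those of ILC1 and conventional NK genes, and fry called 2. Of 18 marker lists of cell types camera called 8, and 0 were called with an estimated correlation or by fry. T cell markers had a median of 0.80 (camera adjusted p = 1.2e-09; adjusted p = 0.210 with an estimated correlation), with 7 of 20 up over the list alone. Cd3g, a chain of the T cell receptor complex that NK cells also transcribe, went from 303 to 553 CPM and Cd3e from 14.9 to 42.3 CPM. NKT and gamma-delta T cell markers summed to 157 ± 8.30 CPM with PBS and 267 ± 24.8 CPM with metformin (SD, n = 3; two-sided exact permutation p = 0.1; camera adjusted p = 1.2e-06; adjusted p = 0.210 with an estimated correlation). Of 7 genes restricted to T cells, the sum was 15.3, 48.4 and 81.6 CPM in PBS 1, 2 and 3 and 166, 94.3 and 36.2 CPM in metformin 1, 2 and 3. B cell markers summed to 1425 ± 204 and 2387 ± 1010 CPM (exact p = 0.2) and plasma cell markers to 1236 ± 1126 and 2973 ± 2167 CPM (exact p = 0.3), with a camera adjusted p of 0.016 and 7.0e-04, both lost with an estimated correlation (adjusted p = 0.756 and 0.662). Metformin 1 held the most of both, 3525 and 5354 CPM. The log2 difference of the B cell sum was 0.67, and 0.35 without metformin 1. That of the plasma cell sum was 1.44, and 0.88 without metformin 1, 0.72 without PBS 3 and 2.18 without PBS 1. Kupffer cell markers summed to 76.6 and 98.7 CPM (exact p = 0.6), with metformin 3 at 148 CPM and a log2 difference of 0.30 that was -0.04 without metformin 3; their camera call (adjusted p = 0.017) was lost with an estimated correlation (adjusted p = 0.662).

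NK cell core markers summed to 28505 ± 1109 CPM with PBS and 32027 ± 2376 CPM with metformin (SD, n = 3; two-sided exact permutation p = 0.1), more than any other marker list in every library; their camera call upward (adjusted p = 0.015) was lost with an estimated correlation (adjusted p = 0.662). Over this list alone Gzmb, Xcl1 and Cd160 rose and Eomes fell, among 18 genes. Basophil and mast cell markers summed to 108 ± 23.3 and 57.2 ± 13.3 CPM (exact p = 0.1; camera adjusted p = 0.0063; adjusted p = 0.210 with an estimated correlation). Monocyte markers summed to 941 and 857 CPM (exact p = 0.5; camera adjusted p = 0.0037; adjusted p = 0.210 with an estimated correlation). The other lists were not called. By the exact permutation test hepatocyte markers summed to 483 and 661 CPM (p = 0.7), neutrophil markers to 206 and 217 (p = 0.8), endothelial markers to 161 and 144 (p = 0.2), stellate cell markers to 127 and 101 (p = 1) and dendritic cell markers to 2179 and 2293 (p = 0.9). Erythroid markers summed to 165 and 160 CPM (p = 0.9), platelet markers to 779 and 709 (p = 0.7), cholangiocyte markers to 61.3 and 68.5 (p = 0.8), ILC2 and ILC3 markers to 301 and 282 (p = 0.3) and the 2 sex-linked genes tested to 108 and 132 (p = 0.5), each by the same exact test. With 1 library left out, log2 differences of the sums ran from -0.14 to 0.59 for hepatocyte and -0.14 to 0.32 for neutrophil markers. Those of stellate cell markers ran from -0.60 to 0.45. The sign also turned for dendritic, erythroid, platelet and cholangiocyte markers, so these directions are not settled.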

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

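The tests with the length and GC trend removed, with the T cell covariate, on the deposited TPM, and with the estimated correlation combined with that trend or with metformin 3 left out were chosen after the results were seen; the others were planned. Values are list medians (log2) unless stated, and the cause was not tested except where named. The count of genes called was 0 in edgeR and 299 by DESeq2, 36 with quality weights, 1 with no filter and 1 with the length and GC trend removed (Tmem273 both times), 0 in the other settings but the replicate block, and 0 to 1 with 1 library left out (Tmem273 without metformin 3, adjusted p = 0.037). Of 81 named genes DESeq2 called 55 and limma-voom with quality weights 16, and Tnfsf10 was called in no setting (0.29 to 0.55, adjusted p = 0.093 to 0.705). Apart from those fixed in advance, named genes were picked by their edgeR p on the same counts. The counts called among them are therefore no separate support. Both groups number their libraries 1 to 3, and whether the numbers pair the samples is not settled. Deviations from the group means correlated at 0.17, 0.076 and 0.17 for equal numbers and at -0.24 to 0.076 for unequal ones. Of 6 libraries 5 matched their own number best, so a shared origin of equal numbers stays open. With the replicate block 3 genes were called, Igkv8-30, Iglc1 and Iglv1, all immunoglobulin genes, named after their values were seen, and 9 lists; cytotoxic (0.15) and glycolysis (-0.068) genes were no longer called. The 11 lists called became 7 with the length and GC trend removed, 2 with an estimated correlation and 2 by fry, 0 with that trend removed and an estimated correlation, 1 without metformin 3 and with an estimated correlation, and 9 to 15 otherwise (9 to 12 with 1 library left out). ILC1 (0.39 to 0.59) and conventional NK genes (-0.57 to -0.38) were called in every setting but these combined ones, where ILC1 genes at 0.56 (adjusted p = 0.086) and 0.49 (adjusted p = 0.095) and conventional NK genes at -0.45 (adjusted p = 0.086, trend removed) were not. Those calls used the preset correlation, apart from the other set tests, which were run on the main fit. The estimated correlation was tried only on that fit (camera adjusted p = 0.047 each) and in the combined settings. With an estimated correlation (adjusted p = 0.366 to 0.616) and by fry (adjusted p = 0.097 to 0.520), which leave fold changes as they are and allow for genes that vary together, the calls were lost for cytotoxic (0.16), inhibitory receptor (0.26), complex I (0.28), complexes II to V (0.26), mitochondrially encoded (0.23), glycolysis (-0.070), cholesterol (-0.25), cell cycle (-0.77) and ribosomal (0.21) genes. Calls were also lost with limma-voom for cytotoxic (0.15) and glycolysis (-0.066) genes, with quality weights for cytotoxic (0.11), glycolysis (-0.052) and mitochondrially encoded (0.035) genes, with DESeq2 size factors for cytotoxic genes (0.16), with no filter for cytotoxic genes (0.15), on TPM for cytotoxic genes (0.015), and with library size only (-0.059), upper quartile scaling (-0.026), the strict filter (-0.056) and protein-coding genes only (-0.053) for glycolysis. With the length and GC trend removed, the calls of cytotoxic (0.075), complexes II to V (0.020) and ribosomal (-0.011) genes were lost, and mitochondrially encoded genes (-0.0066), chemokines (-0.032), antioxidant (-0.031) and FOXO (-0.0061) genes changed direction. Lists not called before were called with DESeq2 for activating receptors (0.10), with upper quartile scaling for activating receptors (0.15), with protein-coding genes only for activating receptors (0.12) and interferon-gamma (0.071), with random lists for activating receptors (0.10) and interferon-gamma (0.054), with quality weights for interferon-gamma (0.066), with no filter for AMPK (-0.12) and transcription factors (-0.10), with the T cell covariate for AMPK (-0.14), FOXO (-0.071), transcription factors (-0.15) and activating receptors (0.10), and on TPM for lysosome genes (-0.14). The direction of the test changed, with no call, with quality weights for antioxidant (0.026), apoptosis (-0.023) and chemokine (0.038) genes, with no filter for apoptosis (0.0058), heat shock (0.10) and type I interferon (-0.024), with the T cell covariate for type I interferon (-0.082), and on TPM for apoptosis (-0.085) and fatty acid oxidation (-0.091). With 1 library left out, medians were 0.080 to 0.17 for cytotoxic genes (call lost without PBS 1, PBS 3, metformin 2 or 3), -0.15 to -0.054 for glycolysis (lost without PBS 2, metformin 2 or 3), -0.025 to 0.34 for mitochondrially encoded genes (lost without PBS 2, PBS 3 or metformin 3), 0.021 to 0.12 for activating receptors (called without metformin 1 or 2), -0.19 to -0.025 for AMPK (called without PBS 1 or metformin 2), -0.19 to -0.014 for transcription factors (called without PBS 1), -0.0031 to 0.12 for interferon-gamma (called without PBS 2 or metformin 3) and -0.23 to 0.095 for type I interferon (called higher without PBS 2 or metformin 3, lower without metformin 2; direction changed without PBS 1 or 3 too). Directions changed, with no call, for cytokine receptors (-0.20 to -0.020, without metformin 3), chemokines (-0.097 to 0.25, without metformin 3), heat shock (0.011 to 0.19, without PBS 3 or metformin 2), apoptosis (-0.053 to 0.059, without PBS 1 or 2) and antioxidant genes (0.013 to 0.15, without metformin 3). Called medians moved by over 1.5 times for cell cycle genes without PBS 1 (-0.45), cholesterol genes without PBS 2 (-0.11) and complex I, complexes II to V and ribosomal genes without metformin 3 (0.16, 0.14 and 0.069), on TPM for inhibitory receptor (0.11), complex I (0.11), complexes II to V (0.086), mitochondrially encoded (0.086), ribosomal (0.039) and glycolysis (-0.19) genes, with quality weights for ribosomal genes (0.11), with the T cell covariate for mitochondrially encoded (0.40) and glycolysis (-0.11) genes, and with the trend removed for complex I (0.065). Among named genes none of which was called, the sign changed for Cd69 (0.070), Gzma (-0.034), mt-Co2 (-0.00040) and mt-Nd3 (-0.13) with the trend removed, Gzma (-0.0080) and Tnfrsf10b (-0.14) on TPM, Ifng (0.0018) with the T cell covariate, Ifng without PBS 1 or metformin 2 (-0.21 to 0.0078) and Tnfrsf10b without metformin 3 (-0.18 to 0.69). As means of log2 CPM, marker differences were 0.12 for ILC2 and ILC3, 0.85 for Kupffer cells, 0.75 for T cells and 0.064 for endothelial cells, a move beyond the spread between replicates, and the other 14 marker lists and all quality measures stayed within it, as did all marker sums with 1 library left out. Tnfrsf10b, near 1 CPM, had a SE above its fold change, and how detection depends on depth was not tested.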

Other observations

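The Reactome and immunoglobulin tests, those with the length and GC trend removed, with the T cell covariate or with an estimated correlation without metformin 3, and those on NK cell core genes without Eomes and on Tnfsf10 against the other ILC1 genes were chosen after the results were seen, as was the use of the PBS 1 result to weigh an explanation. The tests on other splits of the libraries, the estimated correlation and fry on the lists, and the fits with 1 library left out were planned.

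Among 975 Reactome pathways, camera with a preset correlation called 179, 54 higher and 125 lower; 82 of these were also called in the same direction with the length and GC trend removed, and 0 with an estimated correlation. The pathways with the smallest p were sets made largely of immunoglobulin genes, such as classical antibody-mediated complement activation (90 genes, median log2 fold change 1.36, adjusted p = 2.2e-14). Immunoglobulin genes took 0.457%, 0.192% and 0.115% of reads in PBS 1, 2 and 3 and 1.04%, 0.485% and 0.267% in metformin 1, 2 and 3 (two-sided exact permutation p = 0.2, unpaired). For each number the metformin library had the larger share. With the replicate number as a block edgeR called 3 genes, all of immunoglobulin (adjusted p = 0.012 to 0.015). Whether the numbers pair the samples is not settled. Among pathways lower with metformin, resolution of sister chromatid cohesion (116 genes, median -0.22, adjusted p = 1.4e-08) had the smallest p. PD-1 signalling (20 genes, median 0.34, adjusted p = 1.5e-05) was higher, with a median of 0.17 when the length and GC trend was removed (adjusted p = 0.0012). T cell receptor pathways were called higher with it, such as phosphorylation of CD3 and TCR zeta chains (19 genes, median 0.25, adjusted p = 5.5e-05). T cell markers moved with these sets, with a sum of 1204 CPM with PBS and 1815 CPM with metformin (exact p = 0.1). Sums of 7 genes restricted to T cells overlapped between the groups (15.3 to 81.6 CPM with PBS, 36.2 to 166 CPM with metformin). The pathway calls rest on the preset correlation. With an estimated correlation all of them had an adjusted p above 0.05.

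Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 genes called by edgeR, and the highest other gave 1, so all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 1610 genes and the highest other 670, and 1 split, the real one, gave as many. Camera with a preset correlation called 11 lists in the real split and 14 in the highest other, and 4 of the 10 splits gave as many. The count of lists called with a preset correlation thus does not single out the real groups. The gap between the mean log2 fold changes of ILC1 and conventional NK genes was 0.90 in the real split and 0.45 in the highest other, and 1 split gave as wide a gap. Every other split holds libraries of both groups in unequal numbers on each side. It therefore keeps part of the metformin difference, and its lists and gap are not free of that difference.

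ILC1 genes were higher and conventional NK genes lower after metformin, and both lists were called with an estimated correlation (adjusted p = 0.047 each). With an estimated correlation both calls were lost when the length and GC trend was removed (adjusted p = 0.086 each), and the ILC1 call without metformin 3 (median 0.49, adjusted p = 0.095). Carryover of T cells, whose marker sum was also higher, was tested with 7 genes restricted to T cells as a covariate. The ILC1 median stayed at 0.54 (camera adjusted p = 8.0e-18, preset correlation). This argues against cells that express those 7 genes as the whole cause, and covers no other cells. Markers of NKT and gamma-delta T cells summed to 157 CPM with PBS and 267 CPM with metformin (exact permutation p = 0.1). Carryover of those cells was not tested. Dilution of NK cells by cells that lack the NK core genes would lower those genes alike. The NK cell core genes without Eomes had a median of 0.21, with the length and GC trend left in. Its 95% interval, 0.02 to 0.31, is across genes that vary together, so it does not measure the spread between libraries. The call of the core list upward was lost with an estimated correlation (camera adjusted p = 0.662). With the length and GC trend removed the ILC1 and conventional NK medians were 0.56 and -0.45, against 0.54 and -0.44 before. The core genes did not fall as a group, which argues against dilution by cells that lack them. Dilution by cells that express core genes was not covered. The medians with the trend removed argue against that trend as the source of the fold changes. A candidate explanation is a larger share of ILC1 among the cells taken, or a move of NK cells toward the ILC1 state; bulk libraries hold both alike, how the cells were isolated is not given, and which of them applies was not tested. As a hypothesis on Tnfsf10, its higher level may be part of this shift: its log2 fold change lay 0.15 under the median of the other ILC1 genes (difference -0.15, 95% interval -0.54 to 0.24), an interval too wide to say whether it moved as much, so a shared and a separate change cannot be told apart.

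Lists of short genes of energy metabolism and translation had medians above 0 and were called with a preset correlation. Over the list alone edgeR called 5 of 36 genes of complex I, 0 of 41 of complexes II to V, 0 of 13 mitochondrially encoded and 0 of 77 ribosomal genes (14, 18, 1 and 20 higher at an unadjusted p under 0.05), and all 4 list calls were lost with an estimated correlation (adjusted p = 0.554, 0.584, 0.616 and 0.584). With the length and GC trend of each library removed, the medians went from 0.26 to 0.020 for complexes II to V (adjusted p = 0.261), from 0.23 to -0.0066 for mitochondrially encoded genes and from 0.21 to -0.011 for ribosomal genes (adjusted p = 0.458 each), as a trend with gene length would give; the calls ended because the fold changes went to about 0. Complex I went from 0.28 to 0.065; it was called with a preset correlation (adjusted p = 0.0094), while with that trend removed and an estimated correlation 0 of the 26 lists were called. For complex I the trend and a change of its own cannot be told apart. The correction also removes any real change that short genes share, which limits its reading for all 4 lists. A difference in RNA or library quality, strongest in metformin 3, may have set that trend. A response of these genes to a drug that acts on complex I stays open and was not tested.

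Of 40 cell cycle genes 22 fell over the list alone, with the highest score in PBS 1; the call of the list was lost with an estimated correlation (adjusted p = 0.366) and by fry (adjusted p = 0.198). Without PBS 1 the median went from -0.77 to -0.45 and was called with a preset correlation (adjusted p = 3.2e-16), so PBS 1 set part of the size and is argued against as the whole cause. With the length and GC trend removed it was -0.75 (adjusted p = 1.0e-25), which argues against that trend. Fewer dividing NK cells with metformin may be the source, as a hypothesis; dividing cells of another type in the PBS libraries were not tested.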
